A study of Mus musculus with 15 samples.

How the data were processed

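The submitters' notes name Bismark for aligning bisulfite reads to the mm10 build and methylKit for calling methylation, without versions. Each of the 15 libraries came as 1 table of CpG cytosines, kept per strand. Per the table headers, the submitters deposited coverage as read counts after alignment, listing only cytosines with a count of at least 10 and without further normalisation. Per the same headers, the submitters calculated, from those counts, the percent of reads that read C (methylated) and T (unmethylated) at each cytosine. Here, both percentages were converted back to whole read counts. Reads with another base were left out of the level. Percentages were written with 3 decimals in 6 files (wild-type replicates 4 and 5, heterozygous replicates 1, 4, 5 and 8) and with 2 decimals in 9, so values are also given within each kind of file. Both wild-type libraries with 3 decimals were labelled female, so within 3 decimals genotype is partly confounded with sex. Replicate numbers follow the order of the samples in the series within each genotype and pair no animals. For 4 of the 15 libraries, the animal number in the sample title differed from the number in the deposited table's name, and these 4 included wild-type replicate 2 and heterozygous replicate 5. The table of wild-type replicate 2 carried the number in the title of heterozygous replicate 5, that of heterozygous replicate 5 the number in the title of wild-type replicate 3, and that of wild-type replicate 3 the number in the title of wild-type replicate 2. The number of the table of wild-type replicate 1 was in no title.

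Design, tests, gene lists, the rule for named genes and a first set of alternative settings were fixed before the data were examined. Tested cytosines were autosomal, had at least 10 reads in every library and were not above the 99.9th percentile of coverage in any library. Of 2425270 cytosines listed in any library, 1752797 were listed in all 15, and 1711247 entered the comparisons. Tiles were 1000 bases long and held at least 3 tested cytosines, which gave 132208 tiles with a median of 5 cytosines. Gene positions came from the RefSeq table of the same build, which listed 34328 genes without strand. The planned promoter windows were therefore replaced by the CpG-richer gene end, the end of each gene with more listed cytosines within 1000 bases. A tie left out 652 genes and 8838 had no listed cytosine at either end. With at least 3 tested cytosines required, 19306 autosomal gene ends remained. Neither DNA sequence nor exons were used, so methylation at CTCF motifs, at CpG islands and by exon or intron was not analysed here. The H19 control region was read as the 5 kb above the end coordinate of H19, which lies on the minus strand. The other imprinted regions were the 2 kb on each side of the CpG-richer end of their marker gene.

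Counts of methylated and unmethylated reads were fitted per cytosine, tile and gene end with quasi-binomial logistic regression, with sex as covariate. The test was an F test on the deviance. Its dispersion was moderated across features in the way of limma's squeezeVar and held at 1 or more. Adjusted p is Benjamini-Hochberg, with a threshold of 0.05. As other tools, limma was run on log ratios of the counts with 2 reads added, and edgeR on methylated and unmethylated counts. Differences in spread were tested per tile with a moderated linear model on absolute deviations of arcsine-square-root levels from the genotype mean. The genotype by sex term was added to the quasi-binomial regression to test whether the genotype difference depended on sex. Values per library (mean level, outlying cytosines, coverage, gene lists, imprinted regions) were compared by exact two-sided permutation of genotype over all 6435 splits of 15 libraries, or over 1716 splits of 13. The smallest p these allow is 0.000155 and 0.000583. Spread between mice was the mean over pairs of libraries of a genotype of the squared difference in level, after taking off the binomial sampling variance. An outlying cytosine was one more than 20 percentage points from the median of all libraries. Errors are SD over libraries, and the animal is the replicate. Bisulfite reads carried no molecular identifiers, so coverage states counting precision only.

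Planted changes of 20 percentage points were recovered at 89.4% of tiles with 15 libraries and 89.4% with 13, at 98.5% and 92.4% of gene ends and at 51.5% and 33.3% of cytosines, where the simulation held only 155437 and 153301 cytosines, so that the adjustment was lighter than over all tested cytosines. At 10 percentage points, 17.9% and 19.4% of tiles were recovered, 59.7% and 29.9% of gene ends, and 4.48% and 4.48% of cytosines. These changes were planted only at features of middle mean level, none under 20% or above 80%. The shares thus say nothing of power at lower or higher levels. Tested cytosines of gene ends averaged 4.79% in heterozygous and 4.67% in wild-type libraries. Data without a planted change gave 0 calls, and beside planted changes 8 of 80 tile calls, 6 of 119 gene-end calls and 1 of 38 cytosine calls were false with 15 libraries, and 5 of 77, 6 of 89 and 3 of 28 with 13. A planted 6-fold larger SD in heterozygous libraries was recovered at only 3.5% of tiles with 15 libraries and 1.5% with 13, so the tile test of spread had little power.

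After the data were examined, comparisons were run again without wild-type replicate 2 and heterozygous replicate 5, whose sex chromosomes were at odds with the labelled sex. No library was moved to another group. The named-gene rule took the 10 gene ends with the largest rise and the 10 with the largest fall among those that passed, or else the 5 of smallest p in each direction. For tiles it took the 5 largest rises and 5 largest falls beyond 20 Mb of Ctcf, and up to 5 within 20 Mb. For spread it took the 5 tiles of smallest p each way, and for gene lists at most 4 members that passed over the list alone. For gene ends, spread and tiles beyond 20 Mb of Ctcf, genes with only a predicted or clone name (such as Gm and Rik genes) were passed over. The 16 gene lists covered 6 kinds of cell markers (alveolar type 2, alveolar type 1, airway club and ciliated, endothelial, mesenchymal and blood cells), tumour suppressor genes methylated in lung cancer, Hox cluster genes, developmental transcription factors bound by Polycomb, clustered protocadherins, DNA methylation machinery, CTCF and cohesin, germline genes with methylated promoters, xenobiotic metabolism, the Ras and MAP kinase pathway, and housekeeping genes. A list of imprinted control regions was also fixed, of which 20 held at least 3 tested cytosines.

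Tools were Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16.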

Results

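Whole lung DNA from 15 mice was profiled by reduced representation bisulfite sequencing and its enhanced form, assays that read methylation at CpG-rich fragments of the genome. The labels gave 7 libraries as wild-type (3 male, 4 female) and 8 as heterozygous for Ctcf (4 male, 4 female). Ctcf encodes a zinc finger protein that binds insulators and anchors chromatin loops. Each mouse had received a single dose of 1 mg/g urethane, a lung carcinogen, at day 14, and was 46 to 55 weeks old. The series title asks whether disruption of Ctcf destabilises methylation, so level, changed sites and spread between mice were each compared by genotype. Libraries listed between 1817633 cytosines (heterozygous replicate 6) and 2093145 (heterozygous replicate 2), with total coverage of 217363415 to 302342776 reads over cytosines. Median coverage per cytosine ran from 108 to 150 reads by library, and the cytosines tested had a median mean coverage of 146 reads. All coordinates are in mm10.

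Ctcf itself had lower coverage in the libraries labelled heterozygous, at the 8 measured cytosines that lay beyond its promoter (chromosome 8, 105663847 to 105680189). Scaled to a coverage of 10⁶ reads per library, those 8 cytosines took 3.13 ± 0.995 reads (SD, n = 8) in the libraries labelled heterozygous and 5.43 ± 1.04 (SD, n = 7) in those labelled wild-type. The ratio was 0.575 (exact permutation p = 0.00186). Coverage of all 164 measured cytosines in Ctcf, most of them in its promoter, was 112 ± 9.93 scaled reads (SD, n = 8) against 107 ± 4.64 (SD, n = 7), which did not differ by more than the spread between libraries (exact permutation p = 0.365). Within files of 2 decimals the heterozygous libraries had 2.74 scaled reads against 5.33 (exact permutation p = 0.0238), and within files of 3 decimals 3.51 against 5.70, where p = 0.0667 was the smallest an exact permutation could give.

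In 2 libraries, both of which had unlike animal numbers in title and table name, Ctcf and the sex chromosomes were at odds with the labels. The library labelled wild-type replicate 2 had 3.17 scaled reads beyond the Ctcf promoter, where the 6 other wild-type libraries had 5.51 to 6.38. The library labelled heterozygous replicate 5 had 5.25, where the 7 other heterozygous libraries had 1.8 to 3.44. Wild-type replicate 2, labelled male, had X-chromosome gene ends methylated at 26.4%, a level that goes with an inactive X, and listed 300 Y cytosines. Heterozygous replicate 5, labelled female, had 6.60% and 1985 Y cytosines. The other libraries labelled female had an X gene-end level of 27.7% ± 1.04 (SD, n = 7) and 271 to 326 Y cytosines, and the others labelled male 6.73% ± 0.219 (SD, n = 6) and 1915 to 2055. Over all 15 libraries the X level was 25% in females and 9.54% in males (exact permutation p = 0.00326), and without the pair p was 0.000583, the smallest the exact permutation allows. Without the pair, Ctcf coverage beyond the promoter was 2.82 ± 0.544 (SD, n = 7) against 5.81 ± 0.304 (SD, n = 6) scaled reads, a ratio of 0.486 (exact permutation p = 0.000583, again the smallest possible). Group names below are those of the labels, and every direction is by label.

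**Figure D1:**
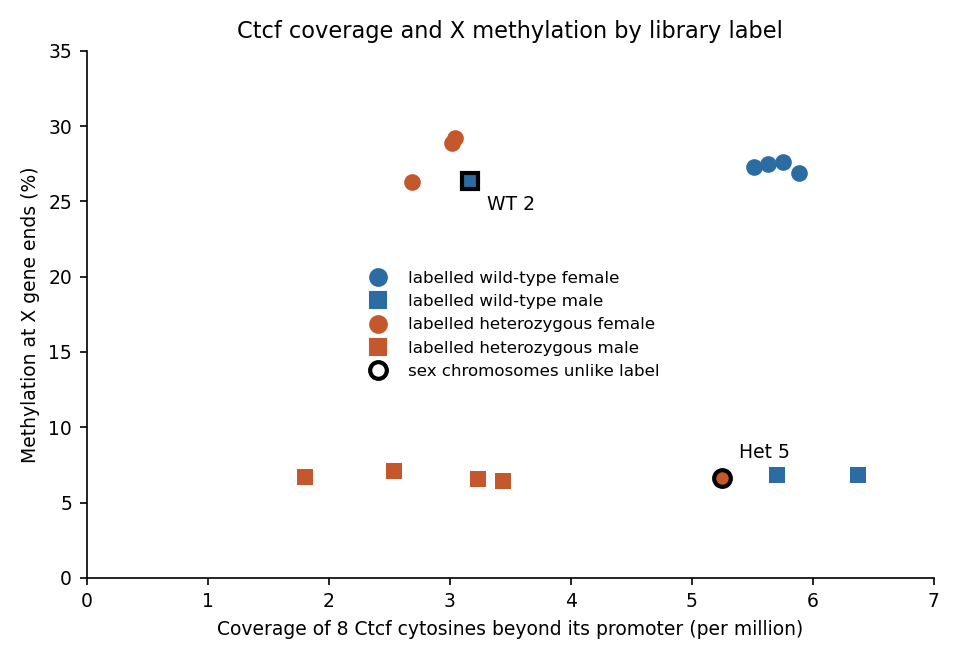
Each point is a library, with reads per 10⁶ at the 8 Ctcf cytosines beyond the promoter on the x axis and the methylation (%) of X-chromosome gene ends on the y axis, by labelled genotype and sex. Wild-type replicate 2 (3.17 reads, 26.4%) sits near heterozygous females, and heterozygous replicate 5 (5.25 reads, 6.60%) nearest wild-type males, though below all other wild-type libraries in reads.

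With all 15 libraries as labelled, no gene end, tile or cytosine changed with genotype. The gene ends of smallest p that were higher in heterozygous libraries were those of Ly6k, a lymphocyte antigen 6 family member, Mest, an imprinted gene expressed from the paternal copy, B3gnt6, an enzyme of mucin O-glycan synthesis, Carmil2, a regulator of actin capping protein, and Sdr16c5, a retinol dehydrogenase. Ly6k (chromosome 15, end at 74799968) had a level of 71.0% ± 5.59 (SD, n = 8) against 58.8% ± 5.57 (SD, n = 7), Mest 69.1% against 59.2%, B3gnt6 65.9% against 44.0%, Carmil2 19.2% against 6.60% and Sdr16c5 75.9% against 70.8%. On the lower side stood Art5, an ADP-ribosyltransferase, Mcoln2, a lysosomal cation channel, Capg, an actin-capping protein, Sec13, a coat protein of secretory vesicles, and Akt1, a kinase of growth signalling. Art5 (chromosome 7, end at 102100291) had 6.63% ± 1.06 (SD, n = 8) against 10.2% ± 1.72 (SD, n = 7), with all 8 heterozygous libraries below all 7 wild-type libraries. Mcoln2 had 2.21% against 3.12%, Capg 9.38% against 12.2%, Sec13 8.14% against 11.1% and Akt1 0.714% against 1.03%. The smallest adjusted p was 0.152, for Art5, and 0.320 for the other 9. With windows of 500 bases Capg differed by -0.441 and Akt1 by -0.0147 percentage points.

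By quasi-binomial regression, 0 of 19305 gene ends, 0 of 132198 tiles and 0 of 1554377 cytosines passed. Unadjusted p was under 0.05 at 1482 gene ends, 11882 tiles and 141066 cytosines, and limma gave 0 at each level and edgeR 0 at the levels it was run on, gene ends and tiles. Among cytosines with a mean level of 5% to 95%, a restriction chosen after seeing the data, 61 passed. Without wild-type replicate 2, 7 gene ends and 68 tiles passed, without heterozygous replicate 5, 2 tiles and 1 cytosine, and without heterozygous replicate 3, 1 gene end and 1 tile.

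Without the pair whose sex chromosomes were at odds with the label, an alternative chosen after seeing the data, 31 gene ends differed by genotype, 24 higher and 7 lower in the 7 heterozygous libraries than in the 6 wild-type. Carmil2 and Gm33578 shared the same cytosines, as did Ccdc151 and Prkcsh, and Cul9 and Srf, so each such window counts as 2 ends. The largest fall was at 4930417O22Rik, which the rule for named genes passes over, from 36.3% ± 1.70 (SD, n = 6) to 29.9% ± 3.75 (SD, n = 7). Its adjusted p was 0.0275 by quasi-binomial regression. Gm41910, also passed over, rose from 48.1% to 60.5%. B3gnt6 (chromosome 7, end at 98192415) rose from 40.2% ± 3.83 (SD, n = 6) to 68.2% ± 5.28 (SD, n = 7), and Carmil2 (chromosome 8, end at 105686010) from 4.72% ± 1.51 (SD, n = 6) to 21.4% ± 4.96 (SD, n = 7). Mest (chromosome 6, end at 30733506) rose from 57.4% ± 1.77 (SD, n = 6) to 70.1% ± 1.88 (SD, n = 7). Sp7 (chromosome 15, end at 102356603), the osteoblast transcription factor osterix, fell from 15.3% ± 1.66 (SD, n = 6) to 10.8% ± 0.831 (SD, n = 7). Adjusted p was 0.000500 for B3gnt6, 0.000190 for Carmil2, 0.000592 for Mest and 0.000190 for Sp7, and at each the 7 heterozygous libraries were apart from the 6 wild-type. Differences within files of 2 and of 3 decimals were 30.5 and 24.2 percentage points at B3gnt6, 15.5 and 18.2 at Carmil2, 11.4 and 14.4 at Mest, and -4.69 and -4.21 at Sp7.

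The other named rises were Olfr658, an olfactory receptor (by 17.5 percentage points), Fam207a (14.4), Tmem150b, a membrane protein (14.3), Mmel1, a membrane metalloendopeptidase (13.9), Agmo, which cleaves ether lipids (13.6), and the overlapping ends of Tpsg1, a mast cell tryptase (11.9), and Cacna1h, a T-type calcium channel (10.2). Named falls were Art5 (from 10.4% to 6.48%), the zinc finger gene Zfp385a (10.6% to 8.09%), the shared end of Cul9, a cullin, and Srf, the serum response factor (5.17% to 2.93%), and H2-Ke6, a steroid dehydrogenase gene of the major histocompatibility region (0.789% to 0.331%). Every one of the 7 heterozygous libraries lay beyond the wild-type mean, and every one of the 6 wild-type libraries short of the heterozygous mean, at each named end, although single libraries of the groups overlapped at Olfr658, Cul9 and Srf. All named ends were called in these same libraries, which favours a like direction in each library and within each kind of file. Such agreement is thus no separate support. Adjusted p of these other named ends ran from 0.00416 (Tmem150b) to 0.0474 (Cul9 and Srf). With 1 of the 13 libraries left out in turn, calls ended in 11 of 13 cases at Art5, Cul9 and Srf, in 9 at Olfr658, Fam207a and Zfp385a, in 8 at H2-Ke6, in 7 at Agmo, in 1 at Mmel1 and Cacna1h, and in 0 at the others named, B3gnt6, Carmil2, Mest and Sp7 included. Gene ends had a median of 5640 reads per library, but the named rises all had fewer. B3gnt6 had 3 cytosines and a median of 610 reads per library, Agmo 3 and 799, Fam207a 4 and 766, and Mest 6 and 1028. The most among the named rises were 23 cytosines and 3949 reads, at Tmem150b. At unadjusted p under 0.05 there were 1969 gene ends. With limma 6 gene ends passed, with edgeR 11, and without moderated dispersion 7, and with 1 library left out 13 to 38. With windows of 500 bases the differences were -0.0844 at Zfp385a (adjusted p = 0.8) and -2.49 at Srf (adjusted p = 0.223), which ended both calls, and -9.03 at Sp7, which passed.

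**Figure D2:**
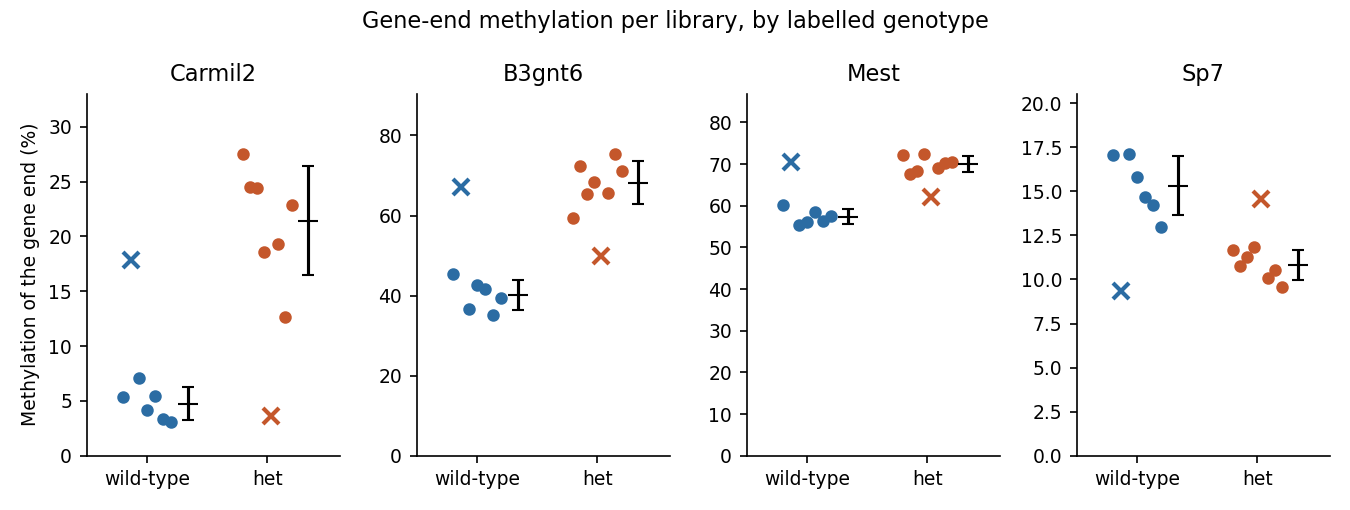
Methylation (%) of the gene ends of Carmil2, B3gnt6, Mest and Sp7, 1 point per library by labelled genotype, with bars for mean and SD of 6 wild-type and 7 heterozygous libraries and crosses for the 2 libraries left out. The crosses at Carmil2 lie at 17.8% (labelled wild-type) and 3.63% (labelled heterozygous).

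Over 1000-base tiles, the same 13 libraries gave 344 tiles that differed by genotype, 279 higher and 65 lower in the heterozygous libraries, with a median size of 11.3 percentage points. The count ran from 181 (without heterozygous replicate 8) to 578 (without heterozygous replicate 3) with 1 library left out, and was 83 without moderated dispersion. The largest rise beyond 20 Mb of Ctcf lay in Pcx, the gene of pyruvate carboxylase (chromosome 19, 4618000 to 4618999), from 30.7% ± 7.92 (SD, n = 6) to 76.2% ± 6.67 (SD, n = 7). Tiles also rose in Osbpl1a, an oxysterol-binding protein gene (by 36.5 percentage points), in Apobec1, the cytidine deaminase that edits Apob mRNA (30), 16328 bases from the long noncoding RNA gene Malat1 (29.1) and in Tmcc3 (28.8). Tiles fell 11850 bases from Pif1, a DNA helicase (35.8% to 17.3%), in Efna2, an ephrin (53.2% to 37.4%), in Myh3, embryonic myosin (59.6% to 44.9%), in Vstm2b (32.6% to 18.9%) and in Nol4l (68.6% to 55.5%). At these 10 tiles, adjusted p was 0.000135 for Pcx and at most 0.0294, for Nol4l, and the 7 heterozygous and 6 wild-type libraries were apart.

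All 344 tiles had the same direction in females and in males, with a median size of 12.5 and 9.19 percentage points. Within files of 2 decimals the median difference in the called direction was 10.5 points (344 of 344 tiles the same way), and within files of 3 decimals, 3 heterozygous against 2 wild-type, 12.2 points (343 of 344). The tiles were called in these same libraries, which favours a like direction within any part of them, so these agreements are no separate support. Fitted within 2 decimals alone, 4 tiles passed. Within 3 decimals both wild-type libraries were labelled female, as was 1 of the 3 heterozygous. With sex as covariate, the genotype term there rests on that 1 heterozygous female, so no count is given. Cytosines that passed numbered 496, of which 460 were higher, a count that ran from 59 (without wild-type replicate 1) to 510 with 1 library left out and was 1 without moderated dispersion. With limma 134 tiles and 269 cytosines passed, and with edgeR 207 tiles. With age beside sex as covariate, 579 tiles and 106 gene ends passed but 0 cytosines by quasi-binomial regression (156949 at unadjusted p under 0.05). The prior degrees of freedom of the moderated cytosine dispersion went from 3.45 to 0.655, and the cause of the lost cytosine calls was not tested.

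**Figure D3:**
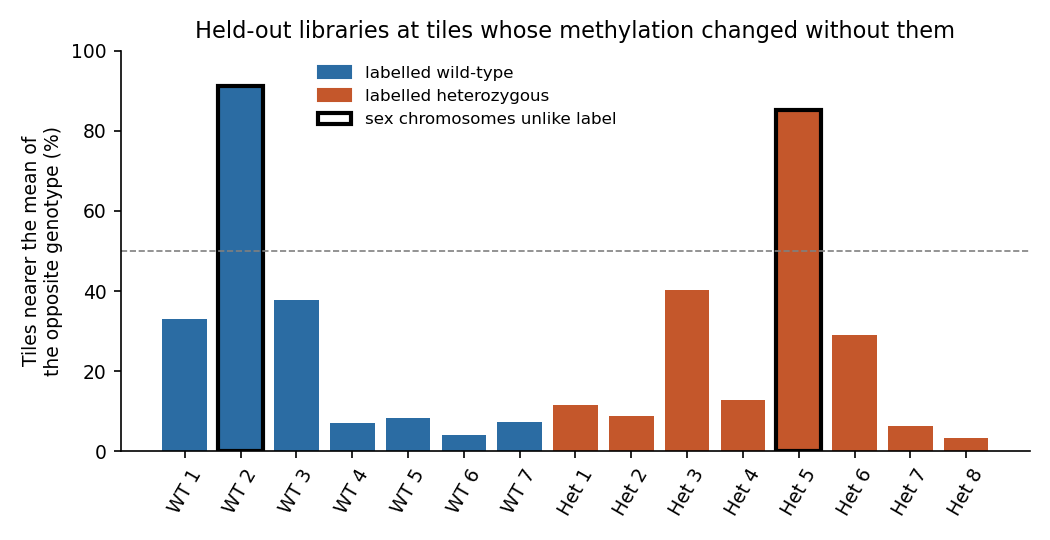
For each library (x axis), the percent of tiles nearer the opposite genotype (y axis), over the tiles called without that library and without the 2 libraries whose sex chromosomes were at odds with the label, with a dashed line at 50. Wild-type replicate 2 (91.3%) and heterozygous replicate 5 (85.2%) lie above it and all others at or below 40.1%.

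Around Ctcf, a group of changed cytosines lay in Carmil2, which starts 3088 bases past the end of Ctcf. In the 13 libraries, 56 of the 116 tested cytosines inside Carmil2 (105686040 to 105694723) passed, and all 56 were higher in heterozygous libraries. The tile from 105694000 to 105694999 in Carmil2 rose from 14.9% ± 6.66 (SD, n = 6) to 52.3% ± 7.18 (SD, n = 7), over 43 cytosines with a median of 6274 reads per library. The Carmil2 tile before it rose from 12.1% to 40.9%, and that from 105688000 from 58.8% to 77.5%. Between them the tile from 105691000 did not pass (72.9% to 77.8%, adjusted p = 0.374), nor did the tile from 105695000 (76.4% to 82.2%, adjusted p = 0.149). Elsewhere within 20 Mb, tiles rose in Adcy7, an adenylate cyclase (48.1% to 76.5%), and in Cnot1, the scaffold of the CCR4-NOT deadenylase complex (48.4% to 70.4%). These 5 tiles had adjusted p of 0.000260 to 0.00617, and all 7 heterozygous libraries lay above the wild-type mean. Inside Ctcf 0 of 130 tested cytosines passed by quasi-binomial regression and 0 by limma, with 11 at unadjusted p under 0.05. Within 20 Mb of Ctcf lay 65 of the 496 cytosines, 4.79 times their share of tested cytosines (95% exact interval 3.75 to 5.99), 56 of the 65 inside Carmil2, and for those 100 kb to 20 Mb away the ratio was 0.760 (0.349 to 1.43). These intervals take each cytosine as independent, which neighbouring cytosines of 1 gene are not, so the first is too narrow. For tiles within 20 Mb the ratio was 1.41 (0.776 to 2.33) and for gene ends 2.73 (0.334 to 9.05), intervals that include 1. The 2 called gene ends within 20 Mb were the same window, listed for both Carmil2 and Gm33578.

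**Figure D4:**
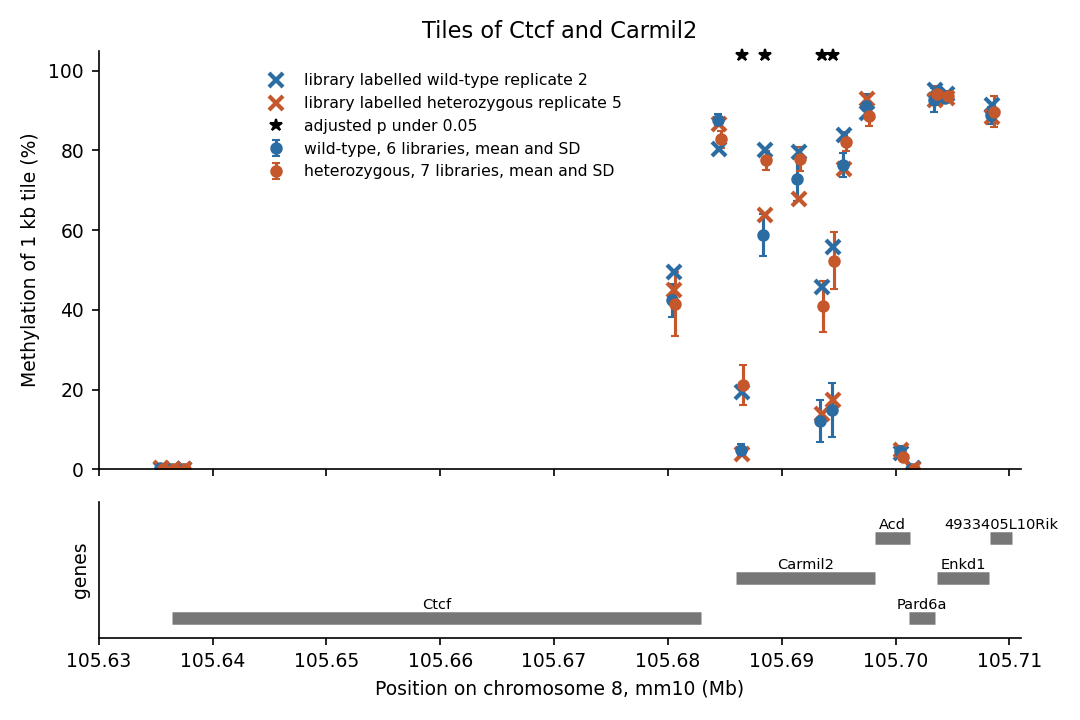
Methylation (%) of 1000-base tiles along chromosome 8 around Ctcf and Carmil2, as mean and SD of 6 wild-type and 7 heterozygous libraries, with the 2 libraries left out as crosses and stars at tiles with an adjusted p under 0.05. In the tile from 105694000 the heterozygous mean was 52.3% and the wild-type mean 14.9%.

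Mean methylation of the tested cytosines did not differ by genotype. Over tested autosomal cytosines it was 32.1% ± 0.684 (SD, n = 8) in heterozygous and 31.8% ± 0.378 (SD, n = 7) in wild-type libraries (exact permutation p = 0.268), and p was 0.249 without the mismatched pair. The difference of 0.333 percentage points turned to -1.03 when cytosines were weighted by reads (exact permutation p = 0.414), and to -1.09 without the pair (p = 0.456). Gene ends had 4.79% against 4.67%, gene bodies 49.9% against 49.4% and intergenic cytosines 64.7% against 64.1%, with an adjusted exact permutation p of 0.305 each. Cytosines of low, middle and high level gave the same adjusted p of 0.305. Within files of 2 decimals the means were 31.9% and 31.9% (exact permutation p = 0.992), and within 3 decimals 32.3% and 31.4% (p = 0.133). Among labelled females heterozygous libraries had 32.1% ± 0.790 and wild-type 31.5% ± 0.116 (SD, n = 4 each, exact permutation p = 0.2), and among males 32.1% ± 0.682 (SD, n = 4) and 32.2% ± 0.0708 (SD, n = 3, exact permutation p = 1).

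Spread of methylation between mice of a genotype, taken here as a measure of instability, did not differ over the whole set. The variance between mice was 29.4 squared percentage points in heterozygous and 28.7 in wild-type libraries (exact permutation p = 0.879), and 29.1 against 28.9 without the pair (p = 0.958). Over pairs of mice of the same labelled sex as well as genotype, the difference was larger, 6.61 squared percentage points more in heterozygous libraries (exact permutation p = 0.139), and 6.44 without the pair (p = 0.227), and did not pass. Intergenic cytosines had 55.7 against 52.9, gene bodies 44.2 against 43.8 and gene ends 6.93 against 6.82 (adjusted p = 0.955 each, exact permutation). Within files of 2 decimals the variance was 30.6 in 4 heterozygous against 25.3 in 5 wild-type libraries (exact permutation p = 0.0317), and within 3 decimals 28.7 against 28.8 (p = 1), and the difference between the kinds of file was not tested. Without the pair the 2-decimal values were 30.6 against 25.5 (exact permutation p = 0.0571) and those of 3 decimals 27.4 against 28.8 (p = 1).

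Outlying cytosines made up 0.682% ± 0.204 (SD, n = 8) of tested cytosines in heterozygous and 0.619% ± 0.349 (SD, n = 7) in wild-type libraries (exact permutation p = 0.688). Within 2 decimals they made up 0.728% against 0.437% (exact permutation p = 0.00794, the smallest possible), and within 3 decimals 0.636% against 1.08% (p = 0.2), so the differences had opposite signs, which was not itself tested. Removal of the pair left 0.735% against 0.456% within 2 decimals (exact permutation p = 0.0286, the smallest possible) and 0.671% against 1.06% within 3 decimals (p = 0.400). These within-file values were looked at after the pooled ones and were not adjusted for their number.

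Single tiles that differed in spread were 13 of 132198, 4 more variable and 9 less variable in heterozygous libraries. More variable were tiles in Ptgds, a prostaglandin D synthase (SD 9.31 against 3.39 percentage points, adjusted p = 0.0351), in Fam110a (9.44 against 1.81), and, at levels near 0, in Kpna1, an importin, and Dtx2, a Notch pathway ubiquitin ligase. A tile near Scaf8, the fifth by p, did not pass (adjusted p = 0.1). Less variable, at levels near 0, were tiles in Camk4, a calmodulin-dependent kinase (adjusted p = 0.00435), Ets2, a transcription factor, Baz1a, a chromatin remodeller subunit, and Dynll2, a dynein light chain. The others of the 9, among them 1 that the rule for named genes takes, are not used here, and nothing is stated about the levels of the less variable tiles as a whole. Kpna1, Dtx2, Camk4, Ets2, Baz1a and Dynll2 had no methylated read in any library of the less variable genotype. Deviations from the mean of each genotype and sex, a setting fixed before the data were examined, gave 60 tiles, and with 1 library left out the count ran from 4 (without wild-type replicate 2) to 18. Without the pair 3 tiles passed, all less variable, and on the percent scale 0 of the 15-library tiles did, with 9348 tiles at unadjusted p under 0.05 in the arcsine-square-root linear model.

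The genotype difference depended on sex at 92 tiles with all 15 libraries and at 319 without the pair. At 88 of the 92, the wild-type females stood farthest from the other 3 groups. In Ubac2, a ubiquitin-associated gene (chromosome 14, 121959000 to 121959999), they had 71.3% ± 1.53 (SD, n = 4), against 48.7% ± 3.71 in wild-type males (n = 3), 46.7% ± 8.15 in heterozygous females (n = 4) and 58.6% ± 1.71 in heterozygous males (n = 4). Cers6, a ceramide synthase gene, had 81.4%, 61.4%, 59.5% and 69.9% in the same order. Both genes were chosen after their values were seen, and the smallest adjusted p was 0.0487. The calls were fragile, since with age as a further covariate 0 tiles passed by quasi-binomial regression (16861 at unadjusted p under 0.05), and without single libraries the count ran from 0 to 2034. Marker genes of alveolar type 2 cells also showed a sex-dependent genotype difference, with gene ends at 5.10% in heterozygous and 4.56% in wild-type females, and 4.28% and 5.06% in males (a difference of 1.33 percentage points between the sexes, adjusted p = 0.0416, exact permutation). Differences of the same sign, not past the threshold, were 1.35 for alveolar type 1 markers, 1.25 for airway markers (adjusted p = 0.0551), 1.75 for endothelial markers (adjusted p = 0.0661) and 1.46 for mesenchymal markers, and the blood cell list had -0.212. All gene ends together had 0.606 (exact permutation p = 0.205). Taken as a ratio to all gene ends, a measure chosen after seeing the data, the alveolar type 2 difference passed (adjusted p = 0.0318, and 0.0286 without the pair, where the endothelial list passed as well), while as a level without the pair it was 1.49 and did not (adjusted p = 0.0571, exact permutation).

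Imprinted control regions, which carry methylation on 1 parental copy, did not differ by genotype as whole regions, and 15 of the 20 measured had a wild-type level of 30% to 60%. Of the rest, 4 had under 5% (Grb10, Impact, Inpp5f and Rasgrf1) and Zdbf2 had 89.4%, levels unlike methylation on 1 copy. At those the lack of a difference says little of the control region. The H19 region (chromosome 7, 142578146 to 142583146), where CTCF binds, had 55.9% ± 2.70 (SD, n = 8) in heterozygous and 54.5% ± 1.15 (SD, n = 7) in wild-type libraries (exact permutation p = 0.235, adjusted p = 0.797). Kcnq1ot1 had 37.7% against 38.8%, Peg3 43.7% against 41.4% and Peg13 41.4% against 38.3%. The Mest region had 57.5% ± 3.09 (SD, n = 8) against 52.6% ± 3.17 (SD, n = 7), with exact permutation p = 0.0118. With adjusted p of 0.236 for Mest and 0.567 or more for the others, 0 of 20 regions passed the permutation test, 1 was at unadjusted p under 0.05, and without the pair 0 passed (adjusted p = 0.186 for Mest). Permuted within each sex, Mest passed with 15 libraries (adjusted p = 0.0327) and not with 13 (0.0762). The narrower window at the Mest gene end, inside that region, did pass without the pair in the regression above (57.4% to 70.1%, adjusted p = 0.000592). Snrpn was not measured.

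Marker genes of lung cell types had like gene-end methylation in both genotypes. Heterozygous and wild-type libraries had 4.69% and 4.77% over 9 alveolar type 2 genes, 17.2% and 16.8% over 12 alveolar type 1 genes, 16.7% and 16.5% over 11 airway club and ciliated cell genes, 7.39% and 6.96% over 13 endothelial genes, 13.1% and 13.1% over 16 mesenchymal genes, and 23.2% and 24.0% over 12 blood cell genes. Adjusted exact permutation p was 0.879 or more for each. No marker gene passed by quasi-binomial regression over all gene ends or adjusted over the list alone, where 6 of 73 had unadjusted p under 0.05. Without the pair, 1 of the 73 rose when adjusted over the list alone, Sox18, an endothelial transcription factor, from 1.36% ± 0.367 (SD, n = 6) to 2.52% ± 0.704 (SD, n = 7), while 0 passed over all gene ends.

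Tumour suppressor genes methylated in lung cancer had 9.13% in heterozygous and 9.18% in wild-type libraries over 34 members, developmental transcription factors bound by Polycomb 3.17% and 2.92% over 87, and Hox cluster genes 6.97% and 6.81% over 38. Clustered protocadherins, cell adhesion genes whose promoter choice involves CTCF, had 40.6% and 39.6% over 35 members, germline genes with methylated promoters 71.5% and 70.4% over 24, and CTCF and cohesin genes 9.51% and 8.99% over 14. DNA methylation machinery had 5.19% and 5.02% over 16, xenobiotic metabolism 18.9% and 18.7% over 12, the Ras and MAP kinase pathway 0.494% and 0.491% over 30, and housekeeping genes 1.78% and 1.84% over 26. Adjusted exact permutation p was 0.879 or more for these 10 lists. The median member difference had the opposite sign to the list mean for alveolar type 2 markers, tumour suppressors and xenobiotic metabolism. With windows of 500 bases housekeeping genes passed, with a difference of -0.179 percentage points (adjusted p = 0.00497, exact permutation).

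Members of these 10 lists passed only without the pair and when adjusted over the list alone, where 2 rose and 3 fell of 316, with 0 over all gene ends by quasi-binomial regression and 41 at unadjusted p under 0.05. Protocadherins Pcdhb13 and Pcdhga8 rose from 61.4% ± 0.885 to 69.8% ± 4.58 and from 37.1% ± 4.01 to 46.7% ± 4.16 (SD, n = 6 and 7), and Pcdhga10 fell from 37.6% to 34.0%. Hoxb1, a hindbrain patterning gene, fell from 19% ± 1.54 to 14.7% ± 1.42, and Hoxc6, a gene of trunk patterning, from 10.8% ± 1.63 to 7.31% ± 1.25 (SD, n = 6 and 7). With all 15 libraries 0 members passed either way, and 30 had unadjusted p under 0.05.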

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

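Chosen only after the result was seen were the tests that leave out the mismatched pair, those of exchanged labels, wrong sex labels and mixed DNA, of distances of 100 kb to 20 Mb from Ctcf, of file decimals, of single cytosines, and of age and cell composition in wild-type females. The splits of 15 libraries and the 20 Mb test around Ctcf were set beforehand.

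Libraries far from the rest of their group were found in 14 of 111 groups tested, where chance gives about 1 in 20 (5.55), and 7 of the 14 concerned wild-type replicate 2 and 6 heterozygous replicate 5. That chance count holds for unselected, independent groups, whereas most gene ends here were named from calls made without this pair, where its libraries are prone to lie apart, and those of Tpsg1 and Cacna1h overlap. Wild-type replicate 2 had 3.17 scaled reads beyond the Ctcf promoter (other wild-type libraries 5.51 to 6.38). Its gene ends were the most methylated of the wild-type libraries at B3gnt6 (67.2%, others 35.2% to 45.5%), Carmil2 (17.8%, others 3.06% to 7.05%), Tmem150b (65.5%, others 48.3% to 53.9%), Mest (70.5%, others 55.5% to 60.2%), Tpsg1 (41.1%, others 22.9% to 27%) and Cacna1h (45.0%, others 27.9% to 32.6%). Heterozygous replicate 5 had 5.25 scaled reads beyond the Ctcf promoter, an X gene-end level of 6.60% and 1985 Y cytosines, against 2.69 to 3.05 reads, 26.3% to 29.2% and 271 to 301 in the other heterozygous females. Among heterozygous libraries it had the lowest Mest level (62.1%, others 67.6% to 72.5%) and the highest at Sp7 (14.6%, others 9.60% to 11.8%) and H2-Ke6 (1.18%, others 0.203% to 0.437%).

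A candidate explanation is that the labels of this pair were exchanged, between a heterozygous female and a wild-type male. At the 344 tiles called without the pair, wild-type replicate 2 was nearer the heterozygous mean at 91.3% and heterozygous replicate 5 nearer the wild-type mean at 85.2%, while among the other 13 libraries, each left out of the calls and means in turn, the highest share was 40.1%. Against a wrong sex label alone, the lower of the shares nearer the labelled genotype was 8.72%. Against mixed DNA of several animals, the X levels of both lay 0 percentage points outside the range of the opposite sex. The deposited tables of both carried the animal number found in the title of a library of the opposite genotype and sex, heterozygous replicate 5 for the first and wild-type replicate 3 for the second. The table of wild-type replicate 3, kept among the 13 libraries, carried the number in the title of wild-type replicate 2, of the same genotype and sex. By number, this is thus no plain exchange within the pair. Titles and tables may have been matched wrongly, though other stages were not tested and the labels were left as given.

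Tiles, gene ends and cytosines called without the pair form a second pattern, with a group of them in Carmil2 beside Ctcf. Among 100 random splits of the 13 libraries, real split included, 1 gave as many tiles (344, highest other 3). Likewise 1 gave as many gene ends (31, highest other 2) and 1 as many cytosines (496, highest other 2). As many calls were thus rare among regroupings of these 13 libraries, a set chosen after seeing the data. The splits cannot tell genotype from anything else that follows the same grouping. With all 15 libraries the real counts were 0, which all 100 splits reach by construction (highest other 6 tiles, 4 gene ends and 1 cytosine). The splits therefore decide nothing there. A processing run marked by file decimals is argued against by 73.5% of the tiles (253 of 344) passing again with decimals as a covariate. For the tiles as a set, a strain variant at a single cytosine is argued against by a median of 100% of a tile's cytosines moving its way. Random tiles had 66.7%, but they were not picked by a genotype difference, which favours a like direction. At 6 of the 344 tiles under 60% of cytosines moved its way (lowest 42%), so such a variant stays open there. A strain variant carried along with the targeted Ctcf allele may account for the calls close to Ctcf, since called cytosines within 20 Mb were 4.79 times their share of tested ones, 56 of the 65 inside Carmil2, but over 100 kb to 20 Mb the ratio was 0.760 (0.349 to 1.43), and for tiles within 20 Mb it was 1.41 (0.776 to 2.33), no excess beyond its interval. The 4.79 rests largely on 1 cluster of neighbouring cytosines, counted as independent, so it is weak evidence for such a variant. What stays open for Carmil2 is the targeted allele itself, a variant next to it, or a lower dose of Ctcf, and no test here separated them.

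Tiles whose genotype difference differed between the sexes form the third pattern, 92 with 15 libraries and 319 with 13, with wild-type females apart from the rest at 88 of the 92. Of 100 splits, real split included, 1 gave as many with 15 libraries (highest other 1) and 1 with 13 (highest other 114). As many calls were thus rare among the splits. Chance is not excluded, as the smallest adjusted p by quasi-binomial regression was 0.0487 and the count hung on single libraries. Without single libraries the 92 became 0 (wild-type replicates 1, 2, 4, 5, 6 and 7, heterozygous replicates 2, 3, 7 and 8), 1 (wild-type replicate 3 or heterozygous replicate 4), 1400 (heterozygous replicate 1), 1086 (heterozygous replicate 5) or 2034 (heterozygous replicate 6). Heterozygous males, the youngest group at a mean of 48.2 weeks, lay short of wild-type females (49 weeks). Over the 92 tiles the median position of heterozygous males was 0.378 of the way from the older groups to wild-type females. Age stays open all the same, since wild-type males had a mean of 53.3 weeks and heterozygous females 51. The term that picked these tiles thus nearly follows age. The older groups also held the mismatched pair, labelled 55 and 54 weeks. The quartiles over tiles were 0.285 and 0.492, which give no uncertainty over mice. With age in the quasi-binomial regression the smallest adjusted p was 0.0561, so the calls ended by a narrow margin. In ordinary least squares on percent levels, a fit other than the one that made the calls, age was added as well. There the median difference went from 21.3 to 24.2 percentage points and the median standard error from 3.81 to 6.07. Wild-type females of unlike file decimals differed by 0.172 of their gap to the other groups, but other pairings of the same libraries, regardless of decimals, also gave a small median value (0.128), and tiles picked by this test have a small spread within groups, so file decimals stay open. A difference in cell composition could contribute and stays open, since alveolar type 2 marker gene ends had a sex-dependent genotype difference of 1.33 percentage points (adjusted p = 0.0416, exact permutation, but 0.0571 without the pair) and all gene ends together 0.606 (p = 0.205), with 4 other cell type lists of the same sign, as does sex itself, which was not tested apart from these.

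Wild-type replicate 3 had the lowest Capg level of the wild-type libraries, 10.3% against 12.0% to 13.2%. Bases other than C or T, which the comparisons do not use, made up 0.0318% of coverage in heterozygous replicate 2, 0.0360% in replicate 3 and 0.0466% in replicate 6, above the wild-type range of 0.0256% to 0.0313%, with no difference by genotype (exact permutation p = 0.807). For the tiles that differed in spread, 3 of 100 splits of 15 libraries gave as many as the real 13 (highest other 14), a share under 0.05 for the libraries as labelled, but without the pair 55 of 100 gave as many as the real 3 (highest other 44), so chance cannot be excluded there. A split with so many more calls than the real one points to a structure of the samples, which was not tested.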

How the results depend on the processing

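Alternatives that leave out the mismatched pair, all those run on the 13 remaining libraries, the limit to levels of 5% to 95%, file decimals as a covariate, and single libraries left out of the sex difference were chosen only after the results were seen. Alternatives on CTCF motifs were not run, nor were CpG islands, exons and introns, because neither sequence nor exon positions were used, and start sites were replaced by gene ends. No paired analysis was possible because replicate numbers pair no animals. Where values changed, the cause was not tested unless stated. Named gene ends without the pair kept their direction in all 344 values, with 95 no longer past the threshold, and named tiles in all 324 with 14. These values rest on the libraries that gave the calls, which favours a like direction. Of 235 values of the 10 gene ends named with 15 libraries, 231 stayed on their side and 4 passed. At this depth, planted changes of 10 percentage points were recovered with 15 libraries at 17.9% of tiles, 59.7% of gene ends and 4.48% of cytosines, the last on fewer cytosines than were tested. No change was planted at a mean level under 20% or above 80%.

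With 15 libraries, the 0 cytosines, tiles and gene ends by quasi-binomial regression (141066, 11882 and 1482 at unadjusted p under 0.05, limma 0 each, edgeR 0 tiles and gene ends) became 496, 344 and 31 without the pair, and 61 cytosines passed among levels of 5% to 95%. With 1 library left out they ran from 0 to 1, 0 to 68 and 0 to 7, as 68 tiles and 7 gene ends without wild-type replicate 2, 2 tiles and 1 cytosine without heterozygous replicate 5, and 1 tile and 1 gene end without heterozygous replicate 3. Other alternatives gave 0 calls.

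Without the pair, the 496 cytosines became 1106 without a covariate, 0 with sex and age (156949 at unadjusted p under 0.05), where moderation of the dispersion was weaker (prior degrees of freedom 0.655 against 3.45), 1 without moderation, 1708 at levels of 5% to 95%, 79 at adjusted p under 0.01 and 25 points, and 269 with limma. The 344 tiles became 579 with sex and age, 83 without moderation, 14 at adjusted p under 0.01 and 25 points, 202 at 10 points, 134 with limma and 207 with edgeR. The 31 gene ends became 106, 7, 1, 12, 6 and 11 in the same order. Fewer libraries lowered most counts. With 1 library left out cytosines ran from 59 to 510, as 59, 67, 267, 272, 232 and 253 without wild-type replicates 1, 3, 4, 5, 6 and 7, and 310, 265, 303, 210 and 167 without heterozygous replicates 1, 2, 6, 7 and 8. Tiles ran from 181 to 578, as 215, 226, 196 and 207 without wild-type replicates 4, 5, 6 and 7, and 578, 192 and 181 without heterozygous replicates 3, 7 and 8. Gene ends ran from 13 to 38, as 20, 16 and 13 without wild-type replicates 4, 6 and 7, and 16 and 13 without heterozygous replicates 6 and 8.

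Tiles with changed spread went from 13 to 60 with deviations from the genotype and sex mean, 0 on the percent scale and 3 without the pair. They ran from 4 to 18 with 1 library left out, as 6, 4, 7 and 6 without wild-type replicates 1, 2, 3 and 6, and 8, 6 and 5 without heterozygous replicates 1, 2 and 4. Without the pair the 3 became 0 at a minimum of 20 reads, 14 with tiles of 500 bases, 45 with the genotype and sex mean and 1 on the percent scale. They ran from 0 to 10 with a further library left out, as 0, 5, 0 and 6 without wild-type replicates 3, 4, 6 and 7, and 1, 9, 9, 8, 1, 1 and 10 without heterozygous replicates 1, 2, 3, 4, 6, 7 and 8.

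The sex difference (92 tiles) became 0 with age as covariate, by quasi-binomial regression with 16861 at unadjusted p under 0.05 and a smallest adjusted p of 0.0561, and 319 without the pair. It ran from 0 to 2034 with 1 library left out, as 1400, 1086 and 2034 without heterozygous replicates 1, 5 and 6, 1 without wild-type replicate 3 or heterozygous replicate 4, and 0 without any other. The 319 became 0 with age (14414 at unadjusted p under 0.05) and ran from 0 to 5898, as 2 and 169 without wild-type replicates 3 and 7, 2851, 35, 30, 103, 5898 and 88 without heterozygous replicates 1, 2, 3, 4, 6 and 7, and 0 without wild-type replicates 1, 4, 5 or 6 or heterozygous replicate 8.

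Mean methylation, higher by 0.333 points in heterozygous libraries, was -1.03 when weighted by reads (exact permutation p = 0.414) and -1.09 without the pair (p = 0.456). With 1 library left out it was 0.248 to 0.488, and without the pair 0.305 to 0.586. The difference in variance between mice (0.693, and 0.259 without the pair) was 6.61 over pairs of the same sex (exact permutation p = 0.139), 6.44 without the pair (p = 0.227), and 2.55 and 2.27 without taking off the sampling variance. It ran from -1.03 to 2.97 with 1 library left out (-1.03 and -0.708 without wild-type replicates 6 and 7). Without the pair it ran from -2.10 to 2.60, negative without wild-type replicates 4 (-0.0932), 6 (-2.10) and 7 (-1.71) and heterozygous replicates 1 (-0.239), 3 (-0.685) and 6 (-0.0498). The difference in outlying cytosines was -0.00174 with reads thinned to 10 and -0.0200 without the pair. It ran from -0.0140 to 0.146 with 1 library left out and from -0.0606 to 0.135 without the pair, negative without wild-type replicates 6 (-0.0140 and -0.0606) and 7 (-0.00607 and -0.0497). None of these passed.

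Permutation within sex gave 1 imprinted region (Mest). Differences turned at Zrsr1 (-0.112 at 20 reads without the pair), Inpp5f (-0.0948 at 20 reads, -0.0194 without the pair) and Zdbf2 (-0.551 without the pair). With windows of 500 bases 1 list passed, housekeeping genes, with 15 libraries and 1, the same, without the pair. Lists that changed sign with 500 bases were alveolar type 2 markers (0.0699, and 0.111 without the pair), blood cell markers (0.712 and 0.901) and tumour suppressors (0.164 and 0.285, and at 20 reads 0.243 and 0.310), and at 20 reads without the pair xenobiotic metabolism (-0.0392). Ctcf coverage, 4.20 scaled reads higher over the whole gene, was -2.31 with its promoter left out (exact permutation p = 0.00186). Higher X methylation in labelled females kept its sign and passed both with all X cytosines and without the pair.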

Other observations

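Chosen only after the result was seen were the counts of tiles called without the mismatched pair and the Polycomb list without it. Tiles with middle levels held most of the genotype differences. Of the 344 tiles, 224 had a mean level of 20% to 80% (65.1%, against 36.1% of tested tiles), 91 a lower level and 29 a higher level. By place, 196 lay in gene bodies (162 higher in heterozygous libraries), 90 between genes (77 higher) and 58 at CpG-richer gene ends (40 higher). Gene ends thus had the largest share of tiles with lower methylation in heterozygous libraries, 18 of 58, against 34 of 196 in gene bodies and 13 of 90 between genes, a difference that was not tested. The 7 heterozygous and 6 wild-type libraries did not overlap at 278 of the 344, which were called in these same libraries, so that count is no separate support. Over all 132208 tiles the groups did not overlap at 686, where chance gives 0.117% of tiles. Of developmental transcription factors bound by Polycomb, 79 of 87 gene ends were higher in heterozygous libraries without the pair and 77 of 87 with it, against 65.4% and 64.7% of all tested gene ends, by a median of 0.326 and 0.229 percentage points, and the list did not pass (adjusted p = 0.592 and 0.879, exact permutation).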
